A study of Mus musculus with 4 samples.

How the data were processed

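Testicular cells of mice at postnatal day 63 were profiled by droplet-based single-cell RNA sequencing, which counts the 3' ends of polyadenylated transcripts with unique molecular identifiers (UMI). Per the labels, 4 samples were made, 2 of the genotype Phf7 f/f and 2 of the genotype Phf7 tKO. Per the labels' protocols, cells were freed from the testes with enzymes, strained, and cleared of red blood cells by lysis. The reads came from 2 instruments, per the labels. The labels do not say whether the samples of a genotype came from separate animals.

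The deposited values are raw UMI counts per gene and cell, per the file headers, which also name Cell Ranger 3.0.2. Per the submitters' processing notes, bcl2fastq 2.19.1.403 and the mouse build mm10 were used. Whether the authors equalised depth between libraries, and which annotation release they used, is not given in the sources used here. The matrix held 28692 genes and 32273 barcodes, with 190744950 UMI in all. The barcodes carried suffixes from 1 to 4, which mark libraries, and no label tied a suffix to a sample or a genotype. Assigning suffixes from the level of Phf7 would have made the outcome define the groups, so no suffix was assigned. The matrix was therefore treated as 1 pooled sample. The planned test between the genotypes in each cell class was not run, and no p-value is given. Values are shown pooled and for each suffix. Intervals are exact Poisson intervals for summed UMI, exact Clopper-Pearson intervals for shares, and exact conditional binomial intervals for ratios, all at 95% and all covering counting error only.

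Cells with at least 500 detected genes and at most 10% mitochondrial UMI were kept. Scrublet, run per suffix in scanpy 1.11.5 with an expected doublet rate of 6%, marked 31 of 29968 cells, or 0.103%. At so low a share the caller did not work, and doublets must be assumed to remain. After removal of the marked cells 29937 were kept. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without the members of the gene lists and without mitochondrial genes, gave 30 principal components, and cells were clustered on 15 shared nearest neighbours with leidenalg 0.10.2 at resolution 1. Leaving out the list genes kept their own values from defining the classes they were compared between. Other genes expressed together with them stayed in, so the comparisons are not independent of the clustering.

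Clusters were named from markers of 13 cell types fixed before the data were examined. The scoring rule was set after the clusters had been seen, and left 21.6% of cells unnamed, or 25%, 23%, 18.8% and 19.8% of suffixes 1 to 4. A marker was detected when at least 5% of a cluster's cells had a UMI, and at least 3 detected markers were required. A cluster took the cell type with the highest mean z-score of log2(CPM + 1) over its markers, if that score reached 0.5 and led the next by 0.05. Clusters stayed unnamed when their median was under 1000 UMI, when germ cell and somatic scores both passed 0.6, or when the markers of another type led. The names end in "like" because they rest on markers alone.

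UMI were summed over the cells of a class and divided by the class total to give CPM. Neighbouring germ cell classes were compared as the log2 ratio of CPM for 214 genes of 13 lists fixed before the data were examined. The lists were transition proteins, protamines and histone variants, histone acetylation, histone ubiquitination and the spermatid proteasome, chromatin remodelling and DNA breaks, the acrosome, the flagellum, synapsis and meiotic recombination, spermatid transcription and mRNA storage, X-linked housekeeping genes, their autosomal retrogenes, X-linked spermatid genes, p53 response and DNA damage, and dissociation stress. H2al2a and Spaca9, 2 further members, were not found under their symbols. A gene was called higher or lower when it differed at least 2-fold in the pool and went the same way in all 4 suffixes. A class with no UMI was set to a floor of 3 counts. Suffixes with under 20 cells in a class were not to be used for the direction, which affected none of the 4 comparisons. The named genes were, per comparison, the 12 highest and the 12 lowest ratios among list members with at least 50 UMI over both classes that went the same way in every suffix, with Phf7, Brdt, Rnf8, Tnp1, Tnp2, Prm1 and Prm2 always included. The value of 1 gene that this rule names is not reported here. For the spread over suffixes, the 5 list members with the largest ratio of the highest to the lowest suffix were named among those with at least 100 UMI in 1 suffix. For shares of cells with a UMI, each cell was also thinned to 1000 UMI. Droplets hold free RNA from other cells, so levels of the always-included genes were set beside those of somatic classes as mean UMI per cell.

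Gene positions came from GENCODE M21 on GRCm38, the same assembly as mm10, in which 28416 of the 28692 gene IDs were found. The ratio step was tested on simulated Poisson counts for the comparison of round spermatid-like with late spermatocyte-like cells. Both classes were drawn from the late spermatocyte-like means at their own depths, with 200 of 10939 genes changed. It recovered 100% of the genes changed by 4-fold up, 3-fold up and 0.25-fold, and 98% of those changed by 0.333-fold. Poisson counts do not vary between cells of a class as real cells do. Computations used python 3.11.15, scipy 1.17.1, scikit-learn 1.9.0 and igraph 0.11.9.

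The alternatives were a minimum of 1000 genes, a mitochondrial limit of 20%, doublets kept, resolutions of 0.5 and 2, list genes allowed in the clustering, each suffix left out, CPM without the 20 most abundant genes of each class, and the median of the suffixes. Removal of the highest 6% of doublet scores, a minimum of 50 UMI, ratios relative to the median gene and means over cells were added after the data had been seen.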

Results

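The study asked, from its title, how PHF7 acts on BRDT and on the exchange of histones for protamines in spermatids. PHF7 is a PHD finger protein of the male germ line, and BRDT is a testis-specific bromodomain protein that binds acetylated histones. The matrix pooled 4 libraries, distinguished only by barcode suffix. Suffix 1 had 8242 barcodes and 46961803 UMI, suffix 2 had 7539 and 44447735, suffix 3 had 7930 and 48982321, and suffix 4 had 8562 and 50353091. No suffix could be tied to Phf7 f/f or Phf7 tKO, so the genotypes were not compared. The comparisons below are between cell classes of the pooled matrix and come with no test, since the 4 unassigned libraries were not taken as replicates. The direction in each library enters every call.

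Germ cells made up most of the cells that could be named. Elongating spermatid-like cells were the largest class, with 10410 of 29937 kept cells (34.8%, exact 95% interval 34.2 to 35.3%). Round spermatid-like cells made up 17.8% (17.3 to 18.2%), late spermatocyte-like cells 11.2% (10.8 to 11.6%), early spermatocyte-like cells 3.38% (3.18 to 3.59%) and spermatogonia-like cells 2.36% (2.2 to 2.5%). Sertoli-like cells, the supporting cells of the tubule, were 4.94%, and Leydig-like cells, which make testosterone, were 1.13%. Macrophage-like, interstitial mesenchymal-like, peritubular myoid-like, endothelial-like and lymphocyte-like cells were 1.22%, 0.815%, 0.498%, 0.204% and 0.0868%. Elongating spermatid-like cells were 31.4%, 30.6%, 38.7% and 38% of the cells of suffixes 1, 2, 3 and 4, and round spermatid-like cells 20.2%, 19.8%, 14.7% and 16.5%. Unnamed cells made up 21.6% of all kept cells, and 25%, 23%, 18.8% and 19.8% of suffixes 1 to 4, most of them in 3 clusters with a median under 1000 UMI. Of these, cluster 0 with 2738 cells scored highest for Sertoli markers, and cluster 23 with 334 cells for Leydig markers. Counted with them, the Sertoli-like share would be 14.1% and the Leydig-like share 2.24%. Cluster 1, with 2437 cells and a median of 877 UMI, scored 0.712 for late spermatocyte and 0.59 for round spermatid markers. Counted with it, the late spermatocyte-like share would be 19.3%. None of the late spermatocyte markers was among its 10 leading genes. The haemoglobin genes Hbb-bs, Hba-a1, Hba-a2 and Hbb-bt led, but 99.2% of all haemoglobin UMI were in 6 barcodes, so these genes do not describe most of its cells. Germ cells named in any class were 69.5% of kept cells, and 88.3% when 1000 genes were required. One late spermatocyte-like cluster of 847 cells had the endoplasmic reticulum chaperone genes Hspa5, Pdia6 and Hsp90b1 among its 10 leading genes, and the interstitial mesenchymal-like cluster included Junb and Fos among its leading genes.

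Phf7 (ENSMUSG00000021902, chromosome 14, 31237689 to 31251317 on the minus strand, GRCm38) was most abundant in spermatocyte-like cells. Its summed UMI gave 586 CPM in early spermatocyte-like cells (570 to 602) and 612 CPM in late spermatocyte-like cells (604 to 621). These intervals cover counting error only, not the spread between libraries. Without suffix 3 the late spermatocyte-like level was 408 CPM. The level was 333 CPM in round spermatid-like (328 to 339), or 197 CPM without suffix 3, 206 CPM in elongating spermatid-like (203 to 209) and 80.4 CPM in spermatogonia-like cells (70.8 to 90.8). Clusters of the same class differed. Early spermatocyte-like clusters 17 and 19 were at 690 and 252.5 CPM, so cluster 19 lay below the round spermatid-like level. Late spermatocyte-like clusters ran from 450 to 745 CPM and elongating spermatid-like clusters from 49.1 to 414 CPM. Somatic classes also held Phf7 UMI, at 226 CPM in Sertoli-like and 24.7 CPM in Leydig-like cells. Counted per cell, late spermatocyte-like cells had a mean of 6 UMI, early spermatocyte-like 4.97, round spermatid-like 2.56 and elongating spermatid-like 1.62. Late spermatocyte-like clusters ran from a median of 1381 UMI in cluster 4 (1955 cells) to 58779 UMI in cluster 28 (201 cells). Round spermatid-like clusters ran from 1494 UMI in cluster 6 (1587 cells) to 31256 UMI in cluster 27 (230 cells). Sums and means of these classes therefore weigh deep cells more, and means per cluster were not computed. As a mean over cells, Phf7 in late spermatocyte-like cells was at 447 CPM. Spermatogonia-like cells had 0.364 UMI per cell (0.321 to 0.411), within the range of the somatic classes, which ran from 0.193 in Leydig-like to 0.447 in macrophage-like cells, so expression above free RNA was not detectable there. The share of cells with a Phf7 UMI was 55.4% of late spermatocyte-like cells at a median of 2175 UMI, 25.8% of Sertoli-like cells at 1090 UMI and 16.9% of Leydig-like cells at 7677 UMI. After thinning to 1000 UMI the shares were 31.9%, 21.8% and 2.67%, with 409, 573 and 0 shallower cells left out. The thinned shares of round spermatid-like cells, 21.3%, and elongating spermatid-like cells, 15.2%, were below that of Sertoli-like cells over all suffixes. By suffix, the thinned round spermatid-like share was 5.68%, 27.9%, 48.8% and 8.76% in suffixes 1 to 4, against 5.88%, 30.7%, 38.9% and 5.8% in Sertoli-like cells, so it was higher in suffixes 3 and 4. The elongating spermatid-like share, 3.95%, 25.2%, 26.8% and 5.97%, was higher in suffix 4 only. Unthinned, the round and elongating spermatid-like shares were 48.1% and 42.9% at medians of 3127 and 5496.5 UMI. If free RNA adds a similar number of UMI to each droplet, thinning removes more of it from deeper cells. The thinned share of Sertoli-like cells, at a median of 1090 UMI, is then no free RNA level for spermatid-like cells. Per cell, the 2.56 and 1.62 UMI of round and elongating spermatid-like cells were above the somatic maximum of 0.447. These are class means over clusters of unlike depth and do not show the level of each cluster.

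Phf7 differed between the libraries in each germ cell class. In late spermatocyte-like cells it was 154, 760, 1155 and 209 CPM in suffixes 1, 2, 3 and 4, and in round spermatid-like cells 75.1, 412, 812 and 108 CPM. The highest suffix was 7.51 times the lowest in late spermatocyte-like, 10.8 times in round spermatid-like and 8.58 times in elongating spermatid-like cells, against a median of 1.2, 1.16 and 1.29 times over the 149, 146 and 128 list members with enough UMI. Phf7 had the largest such ratio of the list members in all 5 germ cell classes. The next in late spermatocyte-like cells was the X-linked Ssxb3, from 6.37 to 13.9 CPM, followed by Slxl1 with 2.07 times, Ssxb2 with 1.87 and Nutm1 with 1.82. The Ssxb and Slx genes have close copies, so their counts are uncertain. In spermatogonia-like cells Zpbp2 followed Phf7 with 2.14 times, and in early spermatocyte-like cells Tex12 with 2.47. In round spermatid-like cells H2afj followed with 1.62 times, and in elongating spermatid-like cells Rpl10l with 2.16. Brdt varied by 1.11 times in late spermatocyte-like cells, 1.08 in round spermatid-like and 1.39 in elongating spermatid-like cells. Prm2 varied by 1.05 times and Tnp2 by 1.09 in elongating spermatid-like cells. Which part of Phf7 is altered in Phf7 tKO is not given in the sources used here, so these 3' end counts cannot show whether a transcript was intact.

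**Figure D1:**
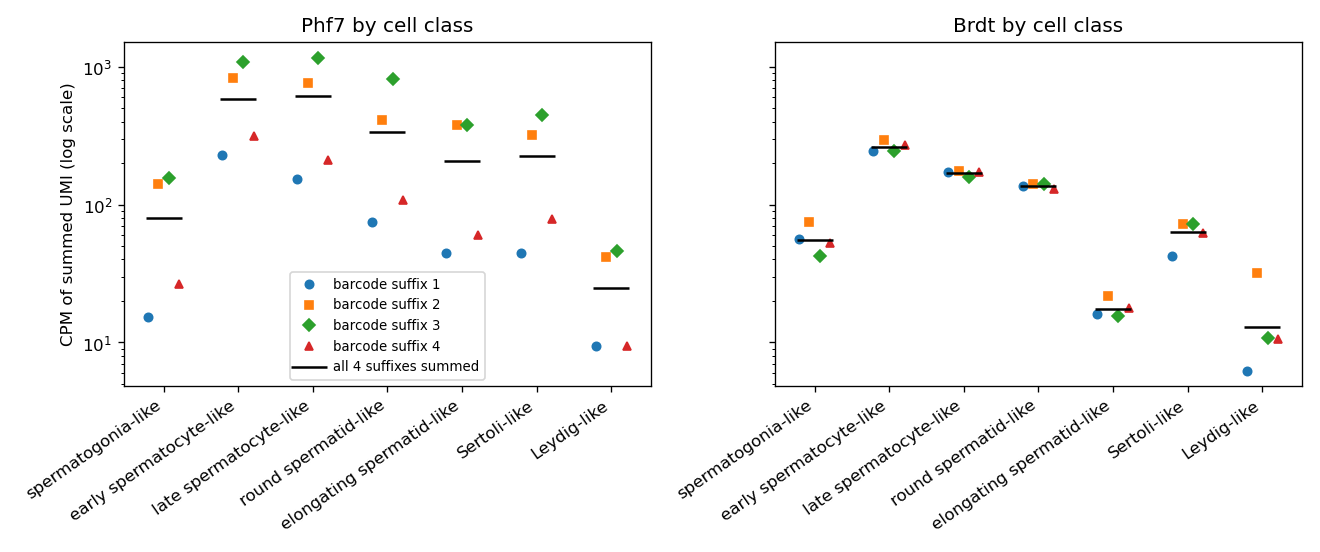
CPM of summed UMI (log axis) for Phf7 and Brdt in 5 germ cell classes and in Sertoli-like and Leydig-like cells; each symbol is 1 barcode suffix and the bar is the sum of all 4. Phf7 in late spermatocyte-like cells ran from 154 to 1155 CPM over the suffixes, while Brdt there ran from 158 to 175 CPM.

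Genes of meiosis were higher in early spermatocyte-like than in spermatogonia-like cells, and X-linked housekeeping genes were lower. Of the 214 list members 58 were higher, 65 lower and 91 neither. In the list of synapsis and meiotic recombination, 13 of 21 were higher and 1 lower, with a median log2 ratio of 1.46. Meiob, which acts in recombination, was higher by a log2 ratio of 4.81 (3.82 to 6.03), Spo11, which makes the meiotic breaks, by 3.69, Sycp2 of the synaptonemal complex by 2.79 and Hormad1 by 2.74. Mybl1, a transcription factor of meiosis, was higher by 5.96 (4.41 to 8.24) on 3 UMI in spermatogonia-like cells, Hist1h1t, the testis linker histone, by 3.20 (1.60 to 5.51), also on 3 UMI, and Psma8, a testis proteasome subunit, by 3.93. Ybx2, which stores germ cell mRNA, Pcgf6 and Pdha2, a retrogene of Pdha1, followed with 3.59, 3.38 and 2.76. The dynein gene Dnah8 was 7.99-fold higher. Phf7 was higher by 2.86 (2.68 to 3.05) and Brdt by 2.22 (2.00 to 2.45), while Rnf8, a ubiquitin ligase of the DNA damage response, was at -0.37. Of 18 genes of spermatid transcription and mRNA storage 9 were higher and 3 lower, of 26 flagellum genes 10 and 5, of 20 acrosome genes 8 and 3, and of 5 autosomal retrogenes 3 and 1. Free RNA was checked only for the always-included genes, so calls of other spermatid genes may reflect it in part. In spermatogonia-like cells, Prm2 was at 16760 CPM in cluster 24 (303 cells, median 1133 UMI), against 3592 and 3171 CPM in clusters 20 and 34. Of 17 X-linked housekeeping genes 15 were lower and none higher, with a median of -2.96. The early spermatocyte-like class joins clusters with unlike shares of X-linked UMI, 0.127% in cluster 17 and 1.26% in cluster 19. Spermatogonia-like cells had 1.76%. The ratios were not computed for each cluster. Atrx was at -4.39, Uba1 at -4.26, Pdha1 at -3.65, Eif2s3x at -3.27 and Rpl10 at -3.23. In the list of p53 response and DNA damage 8 of 10 were lower and 2 higher, the lower including Chek1 at -3.76 and Bax at -3.10. Usp22 and Huwe1 were at -3.77 and -3.46. Of 10 dissociation stress genes 5 were lower, among them Fos, Ier2 and Egr1 at -3.65, -3.09 and -3.08. Prm2 was lower by a log2 ratio of -1.30, while Prm1 at -0.94, Tnp2 at -0.81 and Tnp1 at -0.78 were under 2-fold, with Prm1 lower at -1.05 without suffix 3. At resolution 0.5 the direction turned for Prm2, at 0.58, Prm1, at 0.23, and Tnp2, at 0.01, and it also turned for Prm1 and Tnp2 with the highest doublet scores removed. Prm2 had a mean of 26.1 UMI per cell in spermatogonia-like and 19.9 in early spermatocyte-like cells, within the 13.3 to 41.9 of the somatic classes, so neither level was detectable above free RNA. The number of lower genes was 29 with doublets kept, 28 at resolution 0.5 and 25 with the highest doublet scores removed, and the number of higher genes was 38 at resolution 0.5.

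Genes of synapsis were lower in late than in early spermatocyte-like cells, and most genes of the acrosome list were higher. Of the list members 37 were higher, 70 lower and 107 neither. Of 21 genes of synapsis and recombination 16 were lower and none higher, with a median of -2.40. Dmc1, the meiotic recombinase, was at -6.93 (-7.85 to -6.14), Meiob at -3.91 and Sycp1 at -3.54. Of 20 acrosome genes 12 were higher and 1 lower. Zpbp2 was at 2.27, Zp3r at 2.05, Acrbp at 2.02 (1.96 to 2.09) and Zpbp at 1.95. In the flagellum list 7 of 26 were higher and 19 neither, with Tekt3 at 2.62 and Tekt4 at 2.53. Of 12 X-linked spermatid genes 6 were higher, including Ssxb10 at 3.07 (1.15 to 6.14, 2 UMI in early spermatocyte-like cells), Ssxb1 at 2.93, Ssxb2 at 2.71 and Ssxb3 at 2.62. Nutm1 and Papolb were at 2.04 and 2.03. X-linked housekeeping genes were lower again in 10 of 17, higher in 1 and neither in 6, with Hprt at -7.02, Rpl10 at -3.98 and Rbbp7 at -3.79. The share of X-linked UMI ran from 0.0358% to 0.615% over the late spermatocyte-like clusters, so these ratios depend on the clusters pooled. Top2b, a topoisomerase, was at -6.53, Hist1h2aa at -4.62, Bax at -4.46, Ubr2 at -4.24, Taf7l at -4.22 and H1f0 at -3.66. Rnf8 was lower, with a log2 ratio of -2.34 (-2.58 to -2.10). Its 0.0781 UMI per late spermatocyte-like cell lay within the somatic range of 0.00671 to 0.139, with Leydig-like cells at the upper end. It lay above the 0.00663 (0.00516 to 0.00839) of elongating spermatid-like cells. The somatic classes differ too widely to set a free RNA level for Rnf8. Of 22 genes of histone ubiquitination and the proteasome 13 were lower and 2 higher. Phf7 was at 0.06 (0.02 to 0.11), with suffix 3 above 0 and suffixes 1, 2 and 4 below, and Brdt was at -0.62. The direction of Phf7 also turned under a mitochondrial limit of 20%, at -0.05, without suffix 1, at -0.07, and with list genes allowed in the clustering, at -0.11, and it was at 1.35 with doublets kept. Tnp1 at -0.63, Tnp2 at -0.74, Prm1 at -0.65 and Prm2 at -0.58 were under 2-fold, turned direction under that mitochondrial limit and with list genes allowed, and were within the somatic range per cell in both classes. The number of higher genes was 56 when list genes were allowed in the clustering.

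Many X-linked genes and some genes of the acrosome and flagellum were higher in round spermatid-like than in late spermatocyte-like cells, and many genes of the chromatin remodelling list were lower. Over all lists 70 were higher, 59 lower and 85 neither. The median of 10578 genes lay at -0.36, and relative to it 80 were higher and 45 lower. Of 17 X-linked housekeeping genes 9 were higher, 8 neither and none lower, with Uba1 at 3.99, and 8 of 12 X-linked spermatid genes were higher and 1 lower, the higher including Slx at 3.62. Izumo1, which the sperm needs to fuse with the egg, was at 4.39 (4.26 to 4.53), Spaca4 at 3.92 and Zp3r at 3.78 among the acrosome genes, and Odf3 at 4.09, Fscb at 3.67 and Cabyr at 3.54 among those of the flagellum. Cdyl, a chromodomain protein, was at 4.10, Chd5, a chromatin remodeller, at 3.57, and Fhl5 at 3.79. The heat shock gene Hspa1a was at 4.57. In the flagellum list 11 of 26 were higher and 2 lower, and in the acrosome list 6 of 20 were higher and 4 lower. Of 14 genes of chromatin remodelling and DNA breaks 10 were lower and 1 higher, and 7 were lower relative to the median gene. The lower included Parg at -3.22 and Smarca4 at -3.19. Mlh3, a meiotic mismatch repair gene, was at -4.75, Sycp3 at -3.09, Pcgf6 at -3.17, Psma8 at -3.10, Kat7 at -2.93 and Atr at -2.83. Jun was at -3.85, Gopc at -3.62 and Vps54 at -3.22. Of the 19 transition protein, protamine and histone variant genes 9 were higher and 6 lower. Tnp1, which replaces histones before the protamines, was at 2.06 (2.03 to 2.09), Tnp2 at 2.14, Prm1 at 1.77 and Prm2 at 1.94. Free RNA limits these ratios. Prm2 had a mean of 46.4 UMI per round spermatid-like cell and 15.4 per late spermatocyte-like cell, against up to 41.9 in a somatic class, and Tnp1 had 12.7 and 3.88 against up to 8.44. Rnf8 was lower at -2.30, with 0.0124 UMI per round spermatid-like cell (0.0096 to 0.0158). That lay within the somatic range of 0.00671 to 0.139, which is too wide to set a free RNA level for Rnf8. Phf7 at -0.88 (-0.91 to -0.85) and Brdt at -0.30 were under 2-fold, although Phf7 was lower at -1.05 without suffix 3. Relative to the median gene, Brdt was at 0.06.

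Prm2, Prm1, Tnp1 and Tnp2 had the highest ratios of elongating spermatid-like to round spermatid-like cells, while most other list members were lower. Prm2 was at 6042 CPM in round and 74380 CPM in elongating spermatid-like cells, a log2 ratio of 3.62 (3.62 to 3.63). Prm1 followed at 3.42, Tnp1 at 3.04 and Tnp2 at 3.03. Tnp1 was at 1456 and 679 CPM and Tnp2 at 3335 and 2159 CPM in clusters 5 and 7 (1672 and 1541 cells). These lay below the pooled round spermatid-like levels of 1653 and 3359 CPM, while Prm2 was at 57400 and 137200 CPM there. Tnp1 and Tnp2 were above those levels in the other elongating spermatid-like clusters. The protamines package sperm DNA in place of histones. Prm2 reached a mean of 583 UMI per elongating spermatid-like cell, far above the somatic classes. Also higher were the histone variant H2afb1 at 2.68, the deubiquitinase gene Usp3 at 2.56, Prm3 at 1.60, the spermatid linker histone H1fnt at 1.42, the sperm tail genes Smcp at 2.34 and Akap4 at 1.66, Dmc1 at 1.81 and Actrt1 at 1.26. Over all lists 15 were higher, 146 lower and 53 neither. The 20 most abundant genes took 25.9% of UMI in elongating spermatid-like and 6.82% in round spermatid-like cells, and the median of 10120 genes lay at -1.76, or -1.43 without those genes. Relative to that median, 51 list members were higher and 66 lower. Of 20 acrosome genes 16 were lower, and 11 relative to the median, with Zp3r at -4.52, Zpbp at -4.08 and Dpy19l2 at -4.04. Of 20 genes of histone acetylation 16 were lower, and 8 relative to the median. Epc2 was at -4.97 and Brdt at -2.96 (-3.04 to -2.88), or -1.20 relative to the median gene. Brdt was at 17.6 CPM and 0.138 UMI per elongating spermatid-like cell (0.131 to 0.145). That lay above Sertoli-like cells, at 0.094 (0.0791 to 0.111), but within the somatic range of 0.094 to 0.269 UMI per cell. The upper end of this range rests on 7 UMI in 26 lymphocyte-like cells, so expression above free RNA was not settled. Fsip2, Brca1, Chek1, Ubr2, Sycp1, Taf7l, Rec8 and Tdrd7 were at -4.94, -4.92, -4.78, -4.26, -4.16, -4.14, -4.04 and -4.03. Phf7 was at -0.69 (-0.73 to -0.66) and Rnf8 at -0.93, both under 2-fold, and relative to the median gene they lay at 1.07 and 0.83, so their direction depended on the scaling. Rnf8 was lower at -1.04 without suffix 1 and at -1.13 without suffix 4.

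**Figure D2:**
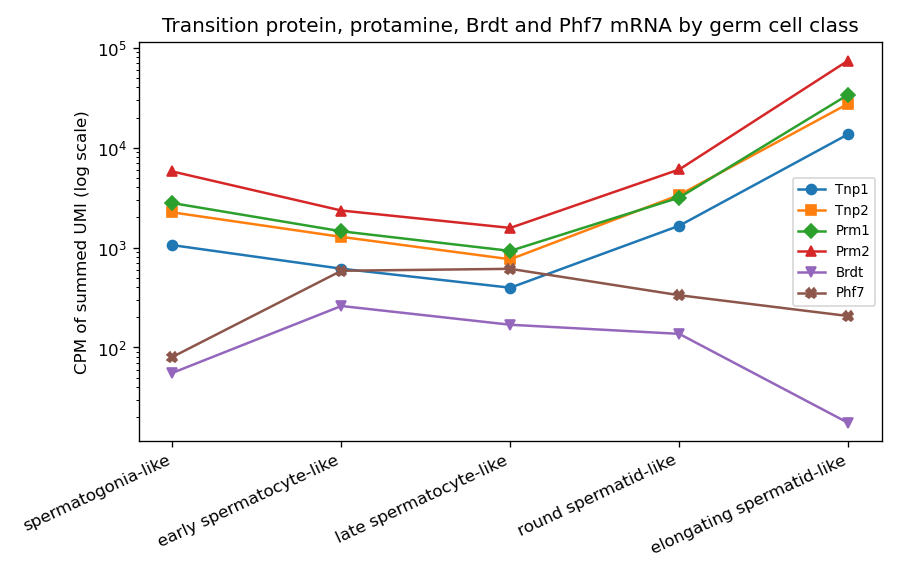
CPM of summed UMI (log axis) of Tnp1, Tnp2, Prm1, Prm2, Brdt and Phf7 in the 5 germ cell classes, pooled over the 4 barcode suffixes; lines join the classes of 1 gene. Prm2 reached 74380 CPM in elongating spermatid-like cells, where Brdt was at 17.6 CPM.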

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

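All tests of this part were chosen only after the result was seen. Signals outside the comparisons came from barcodes that the mitochondrial limit left out and from 1 unnamed cluster. The limit alone left out 2024 barcodes, with a median of 1246 UMI and 14.8% mitochondrial UMI. UMI of all 13 marker sets were present there, some at lower levels than in kept cells. Sertoli markers summed to 5215 CPM, against 240 CPM in kept cells, or 21.7 times as much. The kept cells are pooled over all classes, with most UMI from germ cells, which dilutes Sertoli markers. In Sertoli-like cells alone, Sertoli markers took 1.01% of UMI. The limit may have left out Sertoli cells in particular and lowered the Sertoli-like share of 4.94%, which was not tested. Peritubular myoid markers were at 293.6 CPM (10.1 times their level in kept cells), Leydig markers at 1828 CPM (6.38 times), spermatogonia markers at 304 CPM (3.15 times) and erythrocyte markers at 72.65 CPM (3.06 times). The erythrocyte set also holds Alas2, with 1141 UMI. Of all 3569 haemoglobin UMI, 99.2% were in 6 barcodes, and the left-out barcode among these held 13. Most of the 288 erythrocyte marker UMI here were therefore Alas2, and the value does not show red cells. The markers of early spermatocytes were at 624.6 CPM (1.04 times). Below their level in kept cells were the markers of late spermatocytes at 1424 CPM (0.68 times), of round spermatids at 1429 CPM (0.513 times) and of elongating spermatids at 5709 CPM (0.335 times), and macrophage, interstitial mesenchymal, endothelial and lymphocyte markers at 183.6, 36.58, 7.82 and 8.829 CPM (0.943, 0.711, 0.852 and 0.469 times).

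Cluster 16, with 633 cells, carried both Sertoli and elongating spermatid markers. The cluster was set apart partly by these markers, so their level alone decides nothing about free RNA. Its marker ratios differed in both directions from those in other cells, where free RNA is taken as the source. The same markers are the numerators of these ratios, so the ratios share that limit and do not settle whether free RNA contributed. If its cells were Sertoli cells with free RNA, elongating and late spermatocyte markers would be raised together, but it had 28.8 elongating spermatid marker UMI per late spermatocyte marker UMI (27.9 to 29.7), against 4.51 in Sertoli-like cells and at most 7.81 in another somatic class, in peritubular myoid-like cells. If its cells were elongating spermatids with free Sertoli RNA, Leydig RNA would be raised with it, but it had 164 Sertoli marker UMI per Leydig marker UMI (111 to 254), against 2.98 in elongating spermatid-like cells and at most 14.2 in another germ cell class, in early spermatocyte-like cells. Doublets may contribute, as the median doublet score was 4.83 times that of Sertoli-like cells and 48.7% of the cells lay over the 95th percentile of scores. A high score follows from any mixed profile, however, and the median of 4204 UMI was below the 7053 UMI of random pairs of the 2 classes, so doublets stay open. No biological explanation was tested.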

How the results depend on the processing

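No paired analysis was possible because no label ties a barcode suffix to a sample, as far as genotypes or replicate numbers were concerned. Genotypes and replicate numbers therefore entered no fit. The class comparisons could have been paired by suffix without such a label, since every suffix held cells of each germ cell class. That fit was not run, by choice, since unassigned libraries were not taken as replicates. For lack of labels the DESeq2 test, the replicate block, the removal of each replicate and the unfiltered test of the genotype comparison were not run. Settings added after the data had been seen are removal of the highest doublet scores, the minimum of 50 UMI, ratios relative to the median gene and means over cells. The cause of the changes below was not tested. Class borders depended on the clustering: unnamed cells were 21.6% as reported and 28.9% with doublets kept, although that setting adds only 31 cells. The share of kept cells named as germ cells (cell class shares), 69.5% as reported, was 88.3% with a minimum of 1000 genes, 65.4% with a mitochondrial limit of 20% and also with list genes allowed in the clustering, 63.1% with doublets kept, 63.3% at resolution 0.5, 65.7% at resolution 2 and 61.6% with the highest doublet scores removed. With each suffix left out it ran from 68.8% to 70.4%. Phf7 in late spermatocyte-like cells (Phf7 level by class), 612 CPM as reported, was 642 with doublets kept, 584 at resolution 0.5, 590 with list genes allowed, 587 with the highest doublet scores removed, 669 without the 20 most abundant genes, 484 as the median of the suffixes and 447 as a mean over cells. With each suffix left out it ran from 408 CPM without suffix 3 to 749 CPM without suffix 4. In early spermatocyte-like against spermatogonia-like cells, 58 list members were higher as reported and 38 at resolution 0.5, while 65 were lower as reported, 29 with doublets kept, 28 at resolution 0.5 and 25 with the highest doublet scores removed. In late against early spermatocyte-like cells, 37 were higher as reported and 56 with list genes allowed. In elongating against round spermatid-like cells, 15 were higher and 146 lower as reported, and 51 and 66 relative to the median gene. All other totals of higher or lower genes over all lists were within 1.5 times of those reported.

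Of the ratios of named genes under the alternatives, 1608 kept their direction and call, 17 were no longer called higher or lower, 20 were newly called and 20 changed direction. Of the class shares and Phf7 levels of single germ cell classes, 71 moved beyond their counting interval, and fewer stayed within it. Unchanged results of both kinds numbered 1648, with the 1608 ratios among them. For late against early spermatocyte-like cells, Tnp1, Tnp2, Prm1 and Prm2 turned to 0.098, 0.052, 0.015 and 0.101 with a mitochondrial limit of 20% and to 0.189, 0.073, 0.049 and 0.104 with list genes allowed. Phf7 turned there to -0.047 and -0.112, and to -0.236 as the median of the suffixes. With each suffix left out it ran from -0.075 without suffix 1 to 0.172 without suffix 4. For early spermatocyte-like against spermatogonia-like cells, Tnp2, Prm1 and Prm2 turned to 0.011, 0.23 and 0.582 at resolution 0.5, and Tnp2 and Prm1 to 0.067 and 0.045 with the highest doublet scores removed. Relative to the median gene, Brdt turned to 0.056 for round spermatid-like against late spermatocyte-like cells, and Phf7 and Rnf8 to 1.068 and 0.825 for elongating against round spermatid-like cells. Depth limits genes with few UMI, such as Rnf8 with 66 UMI in round and 69 in elongating spermatid-like cells.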

Other observations

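The count of suffixes tied to a genotype was set after Phf7 had been seen per library, and the other tests of this part before their results were seen. Genes of the X chromosome took 1.76% of UMI in spermatogonia-like cells, 0.399% in early and 0.217% in late spermatocyte-like cells, 1.3% in round and 1.35% in elongating spermatid-like cells. In late spermatocyte-like cells the share was 0.2%, 0.192%, 0.243% and 0.231% in suffixes 1 to 4. These sums mix clusters of unlike depth and share. In early spermatocyte-like cells the share was 0.127% in cluster 17 (575 cells) and 1.26% in cluster 19 (438 cells). In late spermatocyte-like cells it was 0.615% and 0.376% in clusters 4 and 13 (1955 and 847 cells), 0.447% in cluster 29 (195 cells) and 0.0474% and 0.0358% in the deeply sequenced clusters 28 and 30 (201 and 155 cells), so the order of early and late spermatocyte-like cells depends on the clusters compared. Somatic classes ran from 2.17% in peritubular myoid-like to 4.41% in lymphocyte-like cells.

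Phf7 in late spermatocyte-like cells took the values 154, 760, 1155 and 209 CPM in suffixes 1, 2, 3 and 4, with a wide gap between 209 and 760 CPM. Depth does not account for the difference, since the share of these cells with a Phf7 UMI after thinning still differed 5.88 times between the highest and the lowest suffix. Over all barcodes of a library, Phf7 was at 77.4, 470, 635 and 104.5 CPM in suffixes 1 to 4. A different mix of cell classes alone does not account for this, since within late spermatocyte-like cells the CPM still differed 7.51 times. The mix of clusters inside that class was not examined. Genotype stays open and cannot be told apart from other differences between libraries, because 0 suffixes were tied to a genotype.

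Phf7 was not the only gene with large differences between libraries. In late spermatocyte-like cells, 55, 53 and 57 of 6960 genes differed over 2-fold between suffix 1 and suffixes 2, 3 and 4. Between suffixes 2 and 3, 2 and 4, and 3 and 4 there were 24, 13 and 12. Pairs with suffix 1 also had more such genes than other pairs in the other germ cell classes. The genes named here were chosen after their values had been seen. Bloc1s6 on chromosome 2 was at 76.5, 2.27, 76.1 and 83 CPM in round spermatid-like cells of suffixes 1 to 4, and at 50.3, 0.548, 49.1 and 46.3 CPM in elongating spermatid-like cells. On chromosome 5, 4930458D05Rik was at 132, 138, 73.5 and 4.32 CPM in round spermatid-like cells and Gm42792 at 21.4, 24.9, 12.3 and 0.589 CPM, at starts 100840797 and 104239313. On chromosome 6, Ppp4r2 was at 29.1, 192, 195 and 29.7 CPM in elongating spermatid-like cells and Gm44205 at 62.2, 294, 314 and 53.7 CPM, at starts 100833622 and 89269511. On chromosome 17, Dynlt1a was at 76.8, 352, 346 and 330 CPM and Rsph3a at 19.4, 94.4, 81.4 and 78.9 CPM in late spermatocyte-like cells. Dynlt1a and Rsph3a have close paralogs, so their counts are uncertain.

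Haemoglobin UMI numbered 3, 1194, 1420 and 952 in suffixes 1, 2, 3 and 4. Intact red cells are a candidate explanation, since 99.2% of these UMI were in 6 barcodes with 10 or more. Per the labels' protocols red cells had been lysed, so these would be cells that escaped lysis, which was not tested. In 3 unnamed barcodes haemoglobin made up 59.6%, 59.3% and 53% of the UMI. The other 3 held 470 of 2662 UMI in an elongating spermatid-like cell, 123 of 7046 in an endothelial-like cell and 13 of 834 in a barcode left out by the filters. Free RNA does not account for the difference, with 0.7% of the UMI in barcodes that held exactly 1. No biological explanation was tested.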
